A study of Mus musculus with 4 samples.

How the data were processed

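Total RNA from sorted mouse cells was measured on 4 one-colour (Cy3) Agilent expression arrays, 2 of the RFP-positive and 2 of the RFP-negative Flk-1-positive fraction at day 6 of differentiation. The samples were grouped by the labels' reporter status. Per the labels' protocols, RNA was labelled with Agilent's Low Input Quick Amp kit. The intensity values, the scanner's processed signals, were made with Agilent Feature Extraction 10.10.1.1, per the file headers. The 4 arrays lay on 1 slide and in 1 scan, so that neither could be tested as a batch. The deposited value table is linear intensity too. In it each array's processed signals were multiplied by 1 constant, 6.45 and 6.02 for RFP-negative replicates 1 and 2 and 5.82 and 5.39 for RFP-positive replicates 1 and 2. The medians of its columns were 136.2, 143.9, 133.9 and 142.3 in that order. How the constants were chosen is not given in the sources used here.

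Except where an alternative is named, the numbers were computed from the deposited processed signals. Of 62976 spots per array, 3671 control spots were left out. Spots marked by the scanner as not uniform or as population outliers were left out on the array concerned, between 115 and 153 per array. The log2 of the signal minus the log2 of the array's 75th percentile over the 59305 other spots was taken, and spots of the same probe were averaged. The 75th percentiles were 183.2 and 208.1 for RFP-negative replicates 1 and 2 and 206.4 and 249.8 for RFP-positive replicates 1 and 2.

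Probes were named through their RefSeq accession in a RefSeq gene table of assembly GRCm38, without version numbers. Of 55681 distinct probes, 27229 had 1 gene symbol, 0 had several and 28452 had none. These named 20656 genes. For a gene with several probes the one with the highest mean over the 4 arrays was used. A gene was tested if that probe was well above background, by the scanner's own mark, on both arrays of at least 1 fraction, which left 13430 genes. Where a gene was not well above background on either array of a fraction, the difference is given as at least N-fold. For that bound, the mean of the brighter fraction was set against the dimmer fraction's mean of the higher of its own signal and the lowest signal well above background on each array, which was −4.00, −4.22, −3.98 and −4.54 on the log2 scale for RFP-negative replicates 1 and 2 and RFP-positive replicates 1 and 2.

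The fractions were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no block), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Because 2 arrays per fraction give few degrees of freedom, 2 residual and 2.77 from the prior, a count by size was fixed as well, of genes with both RFP-positive arrays at least 2-fold from both RFP-negative arrays. Gene lists were compared with limma's camera, two-sided, with a preset correlation of 0.01 and adjustment over the lists with at least 5 genes tested. The 29 lists hold 539 genes, of which 534 have a probe, and cover 3 groups of Hox paralogues, mesoderm subtypes, blood and endothelium, mural cells, OP9 stroma and fibroblasts, adipocyte differentiation, pluripotency, endoderm, neural ectoderm, 5 signalling pathways, cell cycle, glycolysis, stress and ribosomal proteins. The tests, the lists and the rule for naming genes were fixed before the data were examined.

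Named genes are Hoxb6, Kdr and the Hox genes; the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold, with free places filled by the smallest p among genes at least 2-fold apart between every pair of arrays (unnamed clones, Riken and Gm numbers skipped); up to 4 genes of smallest p per list; and a fixed set of regulators, namely Etv2, Tal1, Runx1, Gata1, Gata2, Cdh5, Pecam1, Nkx2-5, Isl1, Tbx5, Hand1, Cdx1, Cdx2, Cdx4, T, Pdgfra and Pou5f1. Probes without a symbol are counted but not named, and some genes these rules select are not analysed here one by one, though they count in totals and lists.

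The alternatives tried were quantile normalization, scaling to the median, normexp background correction, the deposited value table, no filter and a stricter filter on dim probes, the mean of a gene's probes, eBayes with trend and with trend and robust, the replicate number as a block, each array left out in turn, other thresholds, and other set tests. Normexp used the spots' median signal and median local background with an offset of 50, because the files hold no mean signal. Files were read with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

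The steps were tested on simulated data, 20 data sets of 13430 genes with 200 genes changed in each. With each gene's spread drawn from the fitted prior, the limma fit returned mean log2 changes of 1.00, 2.00 and 3.00 for genes changed 2-fold, 4-fold and 8-fold. At an adjusted p of 0.05 it recovered 0%, 0.924% and 15.1% of them, and 5.91% of the calls were unchanged genes. With each gene's spread set to its fitted value, the version run first, it recovered 1.66%, 76.4% and 95.8%, and 8.63% of the calls were unchanged genes. The version with the drawn spread was added after that share had been seen. In both simulations camera called 0 lists with no list changed. It called the adipocyte list in 100% of data sets after that list had been lowered by 1.4, close to its real median of −1.41. The simulated genes varied independently of each other, so these rates do not cover lists of correlated genes. On the real arrays the correlation within the adipocyte list was estimated at 0.572.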

Results

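Gene expression was measured in cells made from EB5, a mouse embryonic stem cell line, into which a red fluorescent protein (RFP) reporter of Hoxb6 had been introduced. The cells had been cultured for 6 days on OP9, a mouse bone marrow stromal line that serves as a feeder layer, and were then sorted. Both fractions were Flk-1-positive, Flk-1 being the VEGF receptor encoded by Kdr and a marker of early mesoderm. One fraction was positive and the other negative for the reporter. Each fraction was hybridised to 2 one-colour arrays, so that 4 arrays carried the whole comparison, and the number of arrays limited the precision of every value below. All values are log2 signals relative to the array's 75th percentile, errors are SDs over the 2 arrays of a fraction unless named otherwise, and differences are RFP-positive minus RFP-negative.

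Each array held 59305 spots that were not controls. In the RFP-negative fraction 56.2% of them were well above background on replicate 1 and 58.5% on replicate 2. In the RFP-positive fraction the share was 55.2% on replicate 1 and 59.3% on replicate 2. No spot was saturated. Across the 13430 genes tested, which are not independent replicates, the values of the 2 RFP-negative arrays had a Pearson correlation of 0.980, and those of the 2 RFP-positive arrays one of 0.964. RFP-positive replicate 1 correlated at 0.982 with RFP-negative replicate 1 and at 0.974 with RFP-negative replicate 2, both above its value with the other array of its own fraction. RFP-positive replicate 2 had the lowest correlations, 0.953 and 0.950 with the 2 RFP-negative arrays. The SD of the log2 differences between arrays was 0.548 within the RFP-negative fraction and 0.751 within the RFP-positive fraction.

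The genes behind the sort came first, as a check of the labels. The array's single Hoxb6 probe was not well above background on any of the 4 arrays, at −5.97 and −6.17 in the RFP-negative fraction and −5.89 and −6.48 in the RFP-positive fraction. Hoxb6 transcript was therefore not measured, and the reporter labels could not be checked against it. Kdr was strong in both fractions, at 4.25 ± 0.11 (n = 2) in RFP-negative and 4.39 ± 0.03 (n = 2) in RFP-positive cells. Its difference of 0.13 (SE 0.23) was within the error of the limma fit (adjusted p 0.872). A second Kdr probe was also well above background on all 4 arrays and differed by 0.50, with means of 3.64 and 4.13.

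The central comparison asked which genes differed between RFP-positive and RFP-negative Flk-1-positive cells. With limma's moderated test and Benjamini-Hochberg adjustment over 13430 genes, 0 genes passed an adjusted p of 0.05, and the smallest adjusted p was 0.110. At an unadjusted p under 0.05 there were 872 genes, 372 higher and 500 lower in the RFP-positive fraction, where chance alone would give 671.5. Setting the replicates numbered 1 against those numbered 2 gave 758 such genes, and the crossed pairs gave 405. The arrays of the fractions did not overlap for 5418 genes (40.3%), where chance order separates 2 arrays from 2 for 33.3%. Both chance figures are approximate, because the filter also let in genes through 1 fraction alone, which favours separation.

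By size, 183 genes had both RFP-positive arrays at least 2-fold away from both RFP-negative arrays, 63 of them higher and 120 lower. Of these, 57, 21 higher and 36 lower, were well above background on all 4 arrays. For 98 of the 183 the signal of 1 fraction was not well above background on either array, so that only a lower bound of the difference was measured.

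No gene passed the threshold, and the genes of smallest p among those at least 2-fold apart are therefore described by their values only. Where a bound is given, the adjusted p does not belong to it. That p comes from the fit to the signals themselves, including those not well above background. Among the higher ones, 8 of 12 were not well above background on either RFP-negative array. Hoxc4, which had 1 probe, was at least 11.96-fold higher in RFP-positive cells (limma adjusted p 0.110), with an RFP-positive mean of −0.53 ± 0.23 (n = 2). The bounds were at least 3.56-fold for Pou5f2 (limma adjusted p 0.110), 4.74-fold for Bnc1, 3.56-fold for Zfp974, 2.72-fold for Tmem198, 2.25-fold for Fbxo24, 1.68-fold for Hk3 and 1.18-fold for Mzf1. Naip2 was higher by 1.92 and Trim12c by 1.68 on the log2 scale, with 1 of the 2 RFP-negative arrays well above background. Kcna3 and Kcnq1ot1 were measured on all 4 arrays and were higher by 1.70 and 1.52.

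On the lower side, 11 of 12 genes were not well above background on either RFP-positive array. Tex26 was at least 5.63-fold higher in RFP-negative cells (limma adjusted p 0.110). The bounds were at least 3.91-fold for Ttc39b, 3.29-fold for Nckap1l, 2.81-fold for Kcnmb2, 2.22-fold for Zswim3, 1.99-fold for Aldh3b2, 1.85-fold for Rab20, 1.79-fold for Exd1, 1.57-fold for Trarg1, 1.52-fold for Ltb and 1.32-fold for Tnfsf11. Cidec, which encodes a lipid droplet protein, was measured on all 4 arrays. It had a mean of 1.57 ± 0.11 in RFP-negative and −0.97 ± 0.48 in RFP-positive cells (n = 2 each), a difference of −2.54 (SE 0.32, limma adjusted p 0.446). The adjusted p of the 24 genes ran from 0.110 to 0.582.

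Because the reporter belongs to a Hox gene, every Hox gene on the array was read. Of 39 Hox genes with a probe, 14 were not well above background on any array and 12 were on all 4. In all, 16 were tested and 0 passed the threshold over all genes, with an unadjusted p under 0.05 for 3. Hoxc4 was the only one well above background on both RFP-positive arrays and neither RFP-negative array. Hoxb7 and Hoxb8 were well above background on RFP-positive replicate 2 alone, and Hoxc6 on RFP-positive replicate 1 alone. In the other direction, 5 Hox genes were well above background on RFP-negative arrays and no RFP-positive array. These were Hoxc8, on both RFP-negative arrays, and Hoxa2, Hoxa6, Hoxa11 and Hoxd4, on RFP-negative replicate 2 alone. Hoxc5 was lower in RFP-positive cells by −1.27 (SE 0.43), without overlap between the fractions. Hoxc8 was at least 1.44-fold higher in RFP-negative cells. Hoxd1 was at −3.53 on RFP-positive replicate 1, the 1 RFP-positive array that measured it, against an RFP-negative mean of −2.57.

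**Figure D1:**
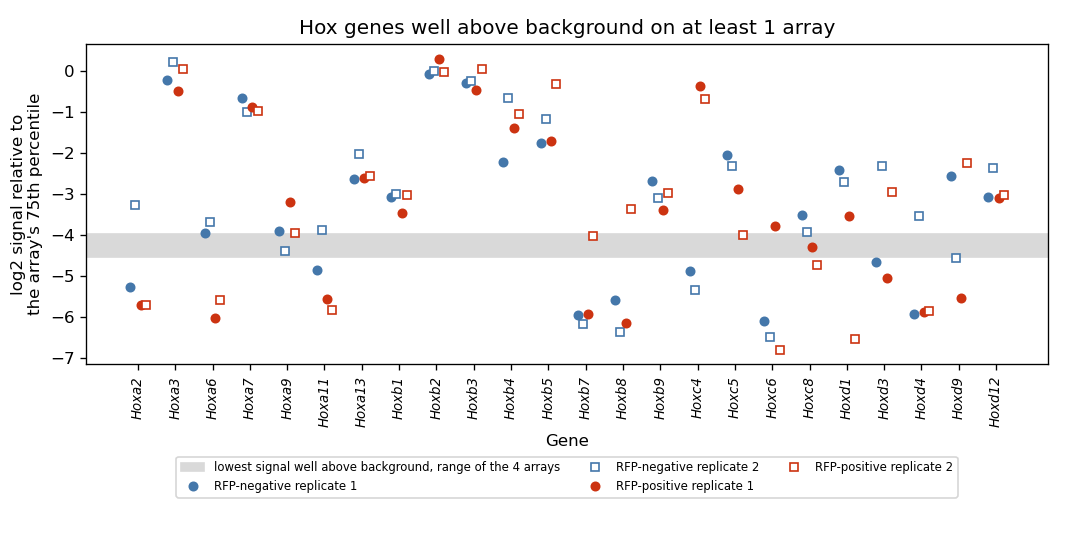
Hox genes well above background on at least 1 array, with the log2 signal of each array relative to its 75th percentile (blue RFP-negative, red RFP-positive; filled replicate 1, open replicate 2). The grey band spans the 4 arrays' lowest signals well above background, from −4.54 to −3.98; values under it are not measured levels, and Hoxc4 is the only gene with both red symbols above the band and both blue ones below.

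The other tested Hox genes overlapped between the fractions. Differences were −0.22 for Hoxa3, −0.10 for Hoxa7, 0.57 for Hoxa9, −0.27 for Hoxa13, −0.20 for Hoxb1, 0.16 for Hoxb2, 0.06 for Hoxb3, 0.21 for Hoxb4, 0.45 for Hoxb5, −0.29 for Hoxb9 and −0.33 for Hoxd12. Except for Hoxa9 and Hoxb9, each of these signs turned when at least 1 array was left out. Of the Cdx genes, which act upstream of the posterior Hox genes, Cdx2 was not well above background on any array, and Cdx1 and Cdx4 were on RFP-positive replicate 2 alone.

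Gene lists for the cell types and pathways of interest were then compared between the fractions with limma's camera test. Of 29 lists, 27 had at least 5 genes tested, and 3 of these passed an adjusted p of 0.05, all lower in RFP-positive cells. With the correlation between genes estimated from the arrays in place of the preset 0.01, 0 lists passed. None of the 3 calls thus holds in that setting. That setting also refers each statistic to the 2 residual degrees of freedom, so the loss cannot be laid to correlation alone. The list for mural cells and smooth muscle had an estimated correlation of 0.0114, near the preset. Its unadjusted camera p still went from 0.00211 to 0.0926. Under the other scalings of the arrays, the medians of the lists for caudal mesoderm, primitive streak, Wnt, Hedgehog and glycolysis changed sign in at least 1, and those of the other lists tested kept theirs. Leaving out 1 array turned some of these too, among them Hox groups 1 to 5, at −0.23 without RFP-positive replicate 2. Without RFP-positive replicate 1 the erythroid median was −0.21, the arterial −0.05 and that of BMP and TGF-beta targets −0.18.

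The adipocyte list was lower by a median of −1.41 over 13 genes (camera adjusted p 7.95e-12). Of its genes, 12 had both RFP-positive arrays below both RFP-negative arrays. Over all genes tested 0 of them passed an adjusted p of 0.05, and 12 did when adjusted over the list alone. The 4 of smallest p were Cfd, Pparg, Fabp4 and Plin4, whose differences were −1.81 (SE 0.24), −1.41 (SE 0.26), −1.58 (SE 0.29) and −1.63 (SE 0.34). Fabp4 was the strongest, with a mean of 4.92 ± 0.08 in RFP-negative and 3.34 ± 0.41 in RFP-positive cells (n = 2 each). With the correlation estimated from the arrays, at 0.572, and 2 residual degrees of freedom, the list had an unadjusted camera p of 0.110.

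**Figure D2:**
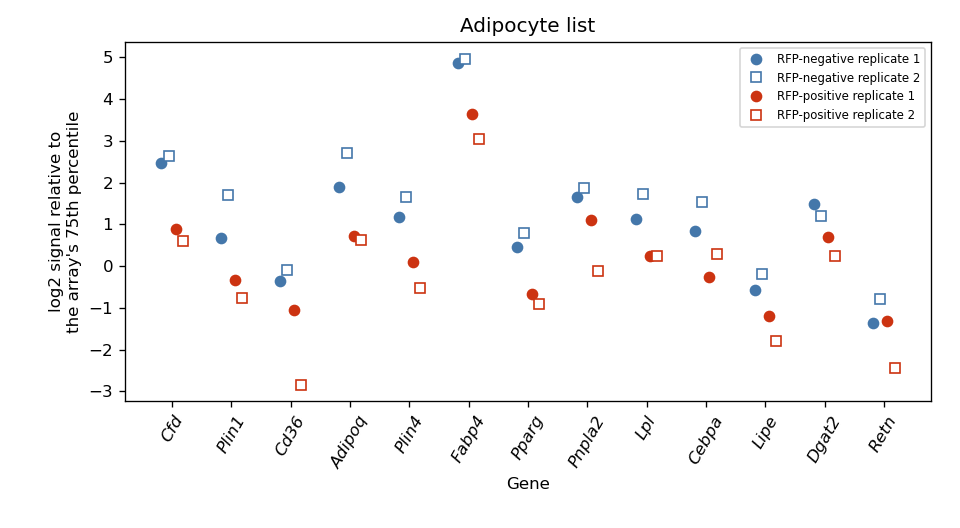
Log2 signal of the 13 genes of the adipocyte list on each array, relative to the array's 75th percentile (blue RFP-negative, red RFP-positive; filled replicate 1, open replicate 2). Both red symbols lie below both blue ones for 12 of the 13 genes.

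The list for OP9 stroma and fibroblasts was lower by a median of −0.72 over 19 genes (camera adjusted p 7.42e-04). Of its genes, 12 were lower and 1 was higher without overlap between the fractions, and 0 passed when adjusted over the list alone. Those of smallest p were Vcam1 at −1.50, Col1a1 at −0.85, Thy1 at −0.89 and Timp1 at −1.09. The list for mural cells and smooth muscle was lower by a median of −0.37 over 12 genes (camera adjusted p 0.0190), with 7 genes lower without overlap and 0 past the threshold when adjusted over the list alone. Its genes of smallest p were Cnn1 at −0.62, Myl9 at −0.79, Actg2 at −0.84 and Acta2 at −0.99. Both of these calls were lost without RFP-negative replicate 2, at an adjusted p of 0.145 for each list, and without RFP-positive replicate 1, at 0.149 for the stromal and 0.339 for the mural list. Without RFP-negative replicate 2 the stromal median shrank to −0.28 and the mural median was −0.32. Without RFP-positive replicate 1 the medians were not smaller, at −0.73 and −0.48.

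The blood and vessel lists did not pass. Haematopoietic progenitor genes were higher by a median of 0.23 over 27 genes (camera adjusted p 0.0816), with 10 genes higher and 3 lower without overlap. Runx1 was higher by 1.54 (SE 0.31), from −2.85 ± 0.28 to −1.31 ± 0.38 (n = 2 each), with a limma adjusted p of 0.635. Cbfa2t3 was higher by 1.24 and Myb by 1.29, while Coro1a was at least 1.71-fold higher in RFP-negative cells. The list's result rested on RFP-positive replicate 1. Without RFP-positive replicate 2 the list passed, with a median of 0.28 and an adjusted p of 0.0159, and without replicate 1 its median turned to −0.042 (adjusted p 0.483). Endothelial genes had a median of 0.09 over 32 genes (camera adjusted p 0.165), with 13 higher and 1 lower without overlap. Flt1 was higher by 0.84, Sox7 by 0.83 and Vwf by 0.56, and Eng was lower by −0.98. Arterial and Notch genes had a median of 0.07 (camera adjusted p 0.668), with Gja4 at 0.46, Notch4 at 0.42, Efnb2 at −0.32 and Dll1 at −0.51. Erythroid genes had a median of 0.02 (camera adjusted p 0.717). Gata1 was higher by 1.44 (SE 0.48) and Alas2 by 0.56, and Nfe2 was at −0.99. The myeloid list had a median of 0.03, a mean of −0.19 and a camera direction downward (adjusted p 0.910), with Cebpa at −1.19 and Tyrobp at 0.48. Cebpa also belongs to the adipocyte list. Of the RFP-positive arrays, replicate 1 alone measured Aif1, at −3.47 against an RFP-negative mean of −2.72, and replicate 2 alone measured Fcer1g, at −0.74 against −3.55. Other regulators of blood and endothelium differed by 0.39 for Tal1, 0.15 for Gata2, −0.72 for Etv2, 0.53 for Cdh5 and 0.29 for Pecam1, with limma adjusted p of 0.922 for Gata2 and lower values for the others, none under 0.75.

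The mesoderm lists did not pass either. Cardiac and pharyngeal genes had a median of 0.12 over 23 genes (camera adjusted p 0.0816), with 8 genes higher and 0 lower without overlap. Tbx5 was higher by 1.28, Tnnt2 by 0.65 and Myl4 by 0.88, while Isl1 differed by 0.02, Hand1 by 0.12 and Nkx2-5 by −0.38. The list for posterior lateral and extraembryonic mesoderm had a median of 0.26 (camera adjusted p 0.333), with Vcam1 at −1.50, Bmp4 at 0.52, Msx2 at 0.60 and Dlk1 at 0.61. The caudal mesoderm list had a median of −0.06, a mean of −0.03 and a camera direction upward (adjusted p 0.981), with Tbx6 at −1.24, Gdf11 at 0.71, Meis2 at 0.49 and Fgf17 at −0.51. For the primitive streak list the median was −0.07, the mean 0.01 and the camera direction upward (adjusted p 0.717). In it, Nodal was at 0.77, Pdgfra at 0.79, Snai1 at −0.79, Mesp1 at −0.74 and T at 0.08. Paraxial mesoderm had a median of −0.11, a mean of −0.02 and a camera direction upward (adjusted p 0.910), with Tcf15 at 0.96, Meox1 at 1.28 and Lfng at −1.45. Intermediate mesoderm had a median of −0.16 (camera adjusted p 0.832), with Sall1 at 0.79, Pax2 at −0.63 and Wt1 at −0.31. The list of Hox paralogue groups 1 to 5 had a median of 0.11 over 10 genes (camera adjusted p 0.668), and 1 gene, Hoxc4, passed when adjusted over the list alone. Its fit used RFP-negative signals that were not well above background. Groups 6 to 9, with 4 genes tested, and groups 10 to 13, with 2, were too small to test and had medians of −0.20 and −0.30.

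**Figure D3:**
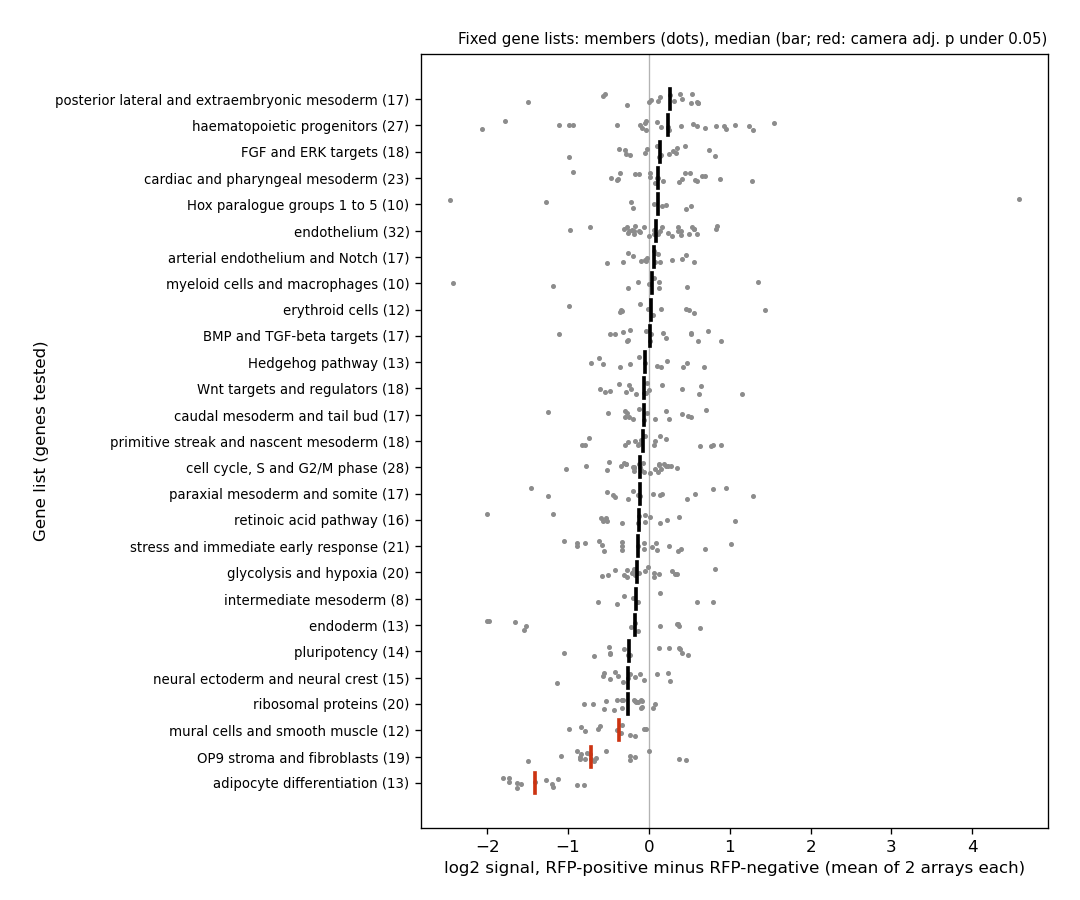
Difference in mean log2 signal, RFP-positive minus RFP-negative, for every tested gene (dots) of the 27 gene lists tested, with the list's median (bars) and the number of genes in brackets. Red bars mark the 3 lists past a camera adjusted p of 0.05, at medians of −0.37, −0.72 and −1.41; the dot farthest to the right is Hoxc4, whose RFP-negative signal was not well above background, so that its position is not a measured size.

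Among the remaining lists, endoderm had a median of −0.17 and a mean of −0.57 (camera adjusted p 0.333). The list's median ran from −0.40 to −0.08 over the alternatives. Its 4 genes of smallest p were all lower in RFP-positive cells, Rbp4 by −2.01, Spink1 by −1.97, Epcam by −1.55 and Cldn6 by −1.52. Ribosomal protein genes had a median of −0.26 (camera adjusted p 0.0816), with Rps2 at −0.80, Rpl13 at −0.69, Rplp1 at −0.56 and Rpl19 at −0.53. The median was −0.02 for RFP-positive replicate 1 and −0.48 for replicate 2 against the RFP-negative mean. Pluripotency genes had a median of −0.25 (camera adjusted p 0.910), with Dppa4 at −0.49, Klf5 at −0.67, Pou5f1 at −1.05 and Tbx3 at 0.39. The Pou5f1 difference was −0.14 without RFP-positive replicate 2. Neural genes had a median of −0.26 (camera adjusted p 0.420), with Neurog1 at −0.57, Pax3 at −0.42, Tubb3 at −0.38 and Sox1 at −0.55. Cell cycle genes had a median of −0.11 (camera adjusted p 0.628), with Ube2c at −0.77, Plk1 at −0.50, Cenpa at −1.02 and Mki67 at −0.52. Glycolysis and hypoxia genes had a median of −0.15 (camera adjusted p 0.717), with Vegfa at 0.82, Pfkl at −0.58, Pgam1 at −0.50 and Hk2 at −0.42. Stress and immediate early genes had a median of −0.14 (camera adjusted p 0.615), with Junb at −1.06, Ier2 at −0.89, Fos at 0.70 and Zfp36 at −0.56.

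The signalling lists had medians near 0. Wnt targets had a median of −0.06, a mean of −0.0046 and a camera direction upward (adjusted p 0.915), with Lef1 at 1.15, Rspo1 at −0.61, Dkk1 at 0.64 and Sfrp5 at 0.63. Targets of BMP and TGF-beta had a median of 0.0077 (camera adjusted p 0.668), with Skil at 0.73 and Id3 at −1.11 beside Bmp4 and Msx2. FGF and ERK targets had a median of 0.13 (camera adjusted p 0.333), with Spry4 at 0.74, Fgf3 at 0.82, Spry2 at −0.99 and Fgf10 at 0.44. Retinoic acid genes had a median of −0.13 (camera adjusted p 0.429), with Cyp26c1 at −1.19, Rarb at 1.07 and Nr2f1 at −0.59 after Rbp4. Hedgehog genes had a median of −0.05 (camera adjusted p 0.930), with Dhh at −0.72, Foxf2 at −0.61 and Gli1 at 0.68. When adjusted over the list alone, 0 genes passed in each of the lists other than adipocyte differentiation and Hox groups 1 to 5. Of the genes named from the lists or the fixed set, Tbx5, Myb, Fgf3 and Hoxa9 were well above background on 1 of the 2 RFP-negative arrays, and Dhh and Foxf2 on 1 of the 2 RFP-positive arrays. Single differences often rested on 1 array. For 50 of 143 named genes, the difference fell below 50% of its value or changed sign when 1 array was left out, and for 28 of the 50 the smallest value was that without RFP-positive replicate 2. Among the genes with differences of at least 0.5 in size given above, these were Acta2, Alas2, Cdh5, Cenpa, Dhh, Dll1, Eng, Etv2, Gli1, Hoxa9, Id3, Klf5, Mesp1, Msx2, Myl4, Nfe2, Nr2f1, Pou5f1, Rarb, Rpl13, Rpl19, Rplp1, Rps2, Sfrp5 and Sox1. In all, 80 of the 143 shrank by over 1.5 times or changed sign without 1 array. Those with differences of at least 1 in size that are not yet named were Cldn6, Cyp26c1, Gata1, Hoxc5, Junb, Lfng, Myb, Spink1, Tbx5 and Vcam1. Gata1 fell to 0.85, Hoxc5 to −0.71 and Cldn6 to −0.77.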

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

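Except for the comparison of the differences between the RFP-negative arrays with those between the fractions, and the count of lists under other splits of the arrays, the tests in this part were chosen after the results they concern had been seen.

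Data outside the main comparison gave the flagged result. Of 12871 probes without a gene symbol that were well above background on both arrays of at least 1 fraction, 147 were at least 2-fold higher on both RFP-positive arrays than on both RFP-negative arrays, and 95 were at least 2-fold lower. The 242 probes together stand against 291 when the replicates numbered 1 were set against those numbered 2, and 184 for the crossed pairs. No biological explanation was tested for these probes.

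The adipocyte genes lower in RFP-positive cells were the clearest pattern. The values argue against scaling of the arrays as the whole source. Over the median, quantile, normexp and deposited scalings the list's highest median was −1.09, with normexp, and quantile normalization gave −1.40. The median and deposited scalings add little, since they move all genes of an array alike. The median over all genes was −0.05 in the main setting, 0.03 with median scaling and 0.01 with the deposited table. A single deviating array is argued against as well, since RFP-positive replicate 1 alone had a list median of −1.28 against the RFP-negative mean, where the median absolute difference between the RFP-negative arrays was 0.387. The 4 arrays can be split into pairs in only 3 ways, too few for a share under 0.05. The real split called 3 lists and the highest of the others 2, so that 1 of the 3 splits, the real one, gave as many. The adipocyte list was not among those called by the other splits, with camera adjusted p of 0.924 and 0.376. Those splits mix the fractions within each group, so a list apart between the fractions could hardly be called there. These values therefore decide nothing about the source.

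RNA of OP9 feeder cells in the RFP-negative fraction was tested with bounds set beforehand. The prediction for feeder RNA as the source was that genes differing most between the RFP-negative arrays would differ most between the fractions. A correlation below −0.3 was to go with it, and one above −0.1 to speak against it. Over the 32 genes of the adipocyte and stromal lists Spearman's rho was 0.10 (bootstrap SD 0.195, two-sided permutation p 0.588, across genes). The second bound was thus passed, by 0.199 and so barely more than the bootstrap SD. Passing it decides nothing, however, because genes that came only from feeder RNA would all shift alike. Their ranks would then be noise, with rho near 0. After the result was seen, a condition that set this bound aside was tried, on the spread of the adipocyte differences. Their SD across genes was 0.330, against a mean SE of 0.362, which left the question open. The condition was then dropped, because the SE holds error that the genes share. Within the lists rho was −0.071 over the 13 adipocyte genes and 0.109 over the 19 stromal genes.

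Other values go with feeder RNA or decide nothing, and a smaller share of feeder RNA was not tested. The stromal list, which shares no gene with the adipocyte list, was lower too, by a median of −0.72. This second test, which unlike the first was chosen after the result, went with feeder RNA. Both lists were higher on RFP-negative replicate 2 than on replicate 1, by medians of 0.387 for the adipocyte and 0.425 for the stromal list. Uneven feeder RNA in that fraction would give this too. The stromal list did not pass without RFP-negative replicate 2 (camera adjusted p 0.145), while the adipocyte list did. Its strongest genes moved unequally, with Fstl1 at −0.18, Sparc at −0.23, Cxcl12 at −0.84 and Col1a2 at −0.68, and these were chosen for their level after it was seen. How many genes of either list the sorted cells express themselves was not determined. Both fractions were sorted on Flk-1, and no array of feeder cells was used here. A difference between the fractions in reporter status, which the design names, stays open as an untested explanation.

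The 183 genes at least 2-fold apart are the next pattern. Of them, 68.9% were not well above background on at least 1 array, against 7.53% of all genes tested. This share decides nothing about weak signals as the source, since a gene that truly differs also falls below background in 1 fraction, and 98 of the 183 were not well above background on either array of 1 fraction. The 3 possible splits of the arrays are too few for a share under 0.05. The real split gave 183 genes and the highest other 156, with 1 of 3 splits, the real one, giving as many. With values below the lowest signal well above background set to that signal, 109 genes remained at least 2-fold apart. By the same measure 4 genes were at least 4-fold apart in the real split, against 5 and 2 in the others. Hoxc4 was the gene farthest apart in the real split, at 3.30 on the log2 scale, and the largest value in the other splits was 2.45 for Meioc. A difference in Hoxc4 between the fractions is an open explanation that these arrays do not test further.

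The lower ribosomal protein genes were not a steady difference between the fractions. The list's median was −0.0232 for RFP-positive replicate 1 and −0.482 for replicate 2 against the RFP-negative mean. RFP-negative replicate 2 was also lower than replicate 1, by a median of −0.241, and the list passed when the replicates numbered 1 were set against those numbered 2. Without RFP-negative replicate 2 the list passed between the fractions as well, at an adjusted p of 0.0350, and without RFP-positive replicate 2 its adjusted p was 0.878. A property of RFP-positive replicate 2 and a shift shared by the arrays numbered 2 cannot be told apart with 1 array of each kind, and a difference between the fractions is untested beside them.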

How the results depend on the processing

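The count of adipocyte genes lower without overlap, the normexp setting, the inclusion of probes without a symbol and the setting of weak values to the background limit were chosen after seeing the data. Normexp on mean signals was not run because the files lack that column, and slide or scan as a block was not run because all arrays share both.

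The count of genes past the adjusted p threshold was 0 under all 13 other settings and all 4 fits without 1 array, in which the lone array is assumed to vary like the other fraction. The smallest adjusted p lay between 0.0787 and 0.998. At an adjusted p under 0.1 there were 108 genes without RFP-positive replicate 1 and 0 in the main setting. Kdr kept its direction throughout, with differences of 0.13 to 0.32 under the 10 other settings, 0.06 to 0.21 with 1 array left out, and an adjusted p of 0.776 or more.

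The count of 183 genes at least 2-fold apart kept within 1.5 times under 7 of 13 settings. Among these, eBayes with trend, eBayes with trend and robust, and the replicate block cannot change a count made without a test. It was 12 with normexp (1 higher, 11 lower), 335 without a filter, 57 with genes well above background on all 4 arrays, 44 at 3-fold, 320 with probes without a symbol and 109 with weak values at the background limit. Quantile normalization gave 72 higher and 99 lower, of which 161 are among the 183. Leaving out 1 array gave 383 to 1471 genes, with the highest count without RFP-positive replicate 1; fewer pairs of arrays then need to differ. The filter changes which genes are counted. Normexp used an offset of 50 added to every signal, which shrinks the log2 differences of weak signals. How much of the fall to 12 genes came from the offset was not tested.

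The 3 lists past the threshold were the same 3 under the quantile, median, normexp and deposited scalings, the mean of probes and the rank test. There were 4 without a filter, 5 with genes well above background on all 4 arrays, 5 with trend, 5 with trend and robust, and 0 with the estimated correlation and 0 with fry, whose smallest adjusted p was 0.429. The added lists were haematopoietic progenitors, higher, and, where there were 5, ribosomal proteins, lower. Leaving out 1 array gave 2 to 5 lists, with 5 without RFP-negative replicate 1, when endoderm (lower) and BMP and TGF-beta targets (higher) were added. The adipocyte list passed in 15 of 17 alternatives, and the mural and the stromal list in 13 each. Of the adipocyte genes, 12 or 13 lay lower without overlap in every setting run for that count. Settings of eBayes and the replicate block cannot change this count either. The cause of these changes was not tested. Both fry and camera with the estimated correlation rest on the 2 residual degrees of freedom, and fry does not compare a list with other genes. With fry the unadjusted p was 0.0398 for the adipocyte and 0.0449 for the mural list.

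The arrays share only a replicate number. The deviations of same-numbered arrays from their fraction means correlated at 0.09 across genes. With the replicate number as a block, 0 genes passed (smallest adjusted p 0.378), and 3 lists passed, the same 3. The block changed no other call.

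Of 143 named genes, 127 kept their direction in every alternative that measured them. With the mean of a gene's probes Dlk1 turned to −0.040 and Hoxb3 to −0.22, and with normexp T turned to −0.0066. With 1 array left out, the differences ranged from −0.12 to 2.81 for Fcer1g, −0.41 to 0.71 for Gata2, −0.58 to 0.035 for Hoxa13, −0.48 to 0.049 for Hoxa3, −0.26 to 0.061 for Hoxa7, −0.43 to 0.028 for Hoxb1, −0.0020 to 0.33 for Hoxb2, −0.21 to 0.32 for Hoxb3, −0.57 to 0.996 for Hoxb4, −0.24 to 1.15 for Hoxb5, −0.68 to 0.015 for Hoxd12, −0.074 to 0.11 for Isl1, −1.01 to 0.25 for Nkx2-5, −0.25 to 0.40 for T and −0.039 to 0.99 for Tyrobp. Signal over background limits the rest: 12419 of the 13430 genes tested were well above background on all 4 arrays.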

Other observations

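RFP-negative replicate 2 had higher values than replicate 1 for several lists, with medians of the difference of 0.58 for endoderm, 0.43 for OP9 stroma and fibroblasts and 0.39 for adipocyte differentiation. RFP-positive replicate 2 had lower values than replicate 1 for endoderm (−0.59), ribosomal proteins (−0.46) and adipocyte differentiation (−0.45).

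With the replicates numbered 1 set against those numbered 2, camera called 2 lists, Hox paralogue groups 1 to 5 and ribosomal proteins, and 46 genes well above background on all 4 arrays were at least 2-fold apart, against 57 between the fractions. The crossed pairs called 0 lists and gave 19 such genes.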
